A study of Mus musculus with 2 samples.

How the data were processed

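Total RNA was measured by sequencing in the hippocampus of male B6CASTF1/J mice, the first-generation cross of the C57BL/6J and CAST/EiJ strains, at 2 months of age. Per the labels, 300 ng of RNA entered each library, RNA was purified with a Norgen kit for animal tissue, and synthetic ERCC spike-in RNAs of the profile for stranded libraries with reduced ribosomal RNA were added. The 2 libraries carry biological replicate numbers 1 and 2 and formed 1 group. That they came from separate animals rests on those numbers, and the strain-level donor label is the same for both.

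Each library had a gene quantification and 2 transcript quantifications. Per the deposited text listings, the gene quantification and the first transcript quantification were derived from an alignment of the reads to the transcriptome, and the second transcript quantification was derived directly from the reads, in both cases with the mm10 mouse genome build and the GENCODE M21 annotation. Per the file headers, the column layout is that of RSEM for the gene and first transcript quantifications and that of kallisto for the second. The programs and their versions are not given in the sources used here. Per the file headers, the deposited expected count is the estimated number of reads assigned to a gene or transcript and need not be whole. Per the file headers, the deposited TPM is the abundance of transcripts scaled to a fixed sum over every entry of a quantification, spike-ins included. Per the file headers, the deposited isoform percent is the share of a gene's TPM in each transcript. The shares reported below were recomputed from TPM so that both quantifications were treated alike. Reads of both parental haplotypes were assigned to the C57BL/6J reference, so reads that carry CAST/EiJ variants can be lost or moved between similar genes, and this was not measured.

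Gene names, types and coordinates came from GENCODE M21 on mm10, in which all 55536 gene identifiers were found. Transcript sequences were matched for all but 86 of them. Where the symbol of a list member belonged to several identifiers, the one with the higher mean TPM was used, while counts over all genes and over gene families kept every identifier. Spike-ins and 26248 entries known by number only were kept out of the gene results. The total expected count was 31422800 in replicate 1 and 31303000 in replicate 2. A count of 0 was read as allowing up to 3 counts, a limit that covers counting error only.

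A gene was called detected at a TPM of at least 1 in both libraries. Pearson and Spearman correlations were computed across genes on log2(TPM + 1) for genes detected in at least 1 library. Genes are not independent replicates. Expected counts were rounded to whole numbers for a chi-square statistic against sampling noise, over genes with a summed count of at least 10, and for the common biological coefficient of variation, estimated with edgeR 4.0.16 under R 4.3.3 with TMM factors and an intercept only. Genes were called different between the libraries at a TPM ratio of at least 2 either way, among genes with an expected count of at least 50 in both. No second group existed, so no groups were tested and no p-values were computed.

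For 47 gene lists, the number of detected members and the median of the members' mean TPM were taken, with the percentile of that median among 10000 random lists of the same size drawn from detected genes. The median log2 TPM ratio of replicate 2 over replicate 1 was taken over members with an expected count of at least 50 in both libraries. Its percentile came from 10000 random lists of the same size matched on mean expression in 20 bins, and lists under percentile 2.5 or over 97.5 were named. Transcripts were compared between the quantifications on log2(TPM + 1) over transcripts above 0 in either. The most abundant transcript was compared over detected genes with more than 1 transcript. Isoform shares were taken for fixed genes with a mean TPM of at least 10.

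The groups, tests, thresholds, lists and main alternatives were fixed before the data were examined. Genes were named by a fixed rule. It took the 10 nuclear protein-coding genes and the 5 other genes with the highest mean TPM, the 3 members of each list with the highest mean TPM, all members of lists of at most 7, members at least 2-fold apart, the 10 largest ratios in each direction, and the isoform genes. Some genes that the rule names are not reported here. Members of the shifted lists beyond that rule were named after their values were seen. Coordinates are those of the annotation on mm10. Replicates could not be tested as separate animals, and intervals of TPM given by the authors within a library were not used here. The alternatives covered the detection threshold, the pseudocount, filters on low values, the scaling, the second quantification and leaving out each library.

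The dispersion estimate was tested on simulated data. For simulated libraries of all genes, true coefficients of variation of 10% and 20% gave estimates of 9.91% and 19.8%, and a true value of 0 gave 0.988%. For simulated spike-ins, 10% gave 7.49% and 20% gave 21.4%. The list percentile was tested with lists of 12 members in counts simulated for 13916 genes. It called 4 of 50 lists with no shift, and 50 of 50 lists at a log2 shift of 0.2. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.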

Results

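Total RNA from the hippocampus of male B6CASTF1/J mice was profiled in 2 libraries that form 1 group, so the data give a reference profile of the tissue and no treatment or genotype was compared. Per the labels the tissue is a layer of the hippocampus, the brain region whose dentate gyrus and CA fields hold granule and pyramidal neurons. The total expected count was 31422800 in replicate 1 and 31303000 in replicate 2. Values below are the mean ± SD of the 2 libraries (n = 2) in TPM unless another unit is named.

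By mean level a neuronal gene headed the protein-coding profile, among widely expressed genes such as Actb and Gapdh. Camk2a, the alpha subunit of calcium/calmodulin-dependent kinase II, had the highest mean nuclear protein-coding level at 1437 ± 92.8 TPM, and lies on chromosome 18 from 60925618 to 60988152 in mm10. Hpca, a neuronal calcium sensor named for the hippocampus, reached 1044 ± 21.1 TPM. Others among the 10 highest were Actb at 1351 ± 38.7 TPM, which was above Camk2a in replicate 2, Fth1 at 1298 ± 10.3 TPM, Eef1a1 at 1260 ± 14.5 TPM, Cpe at 1145 ± 12.6 TPM, Aldoa at 1127 ± 35.5 TPM, Gapdh at 1032 ± 1.20 TPM and Snurf at 949 ± 32.0 TPM. In the second quantification Gapdh, Actb and Eef1a1 were above Camk2a, at 3690, 3061 and 2508 against 2473 TPM. Snurf shares its transcript with Snrpn and had 0 TPM in the second quantification in both libraries, so its level is uncertain. In all, 14560 genes were detected, of which 12710 were protein-coding, which is 57.7% of the 22028 annotated protein-coding genes.

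Short noncoding RNAs held a large part of the transcript molecules but few of the reads. The signal recognition particle RNA genes Rn7s1 and Rn7s2 were at 160475 ± 1846 TPM each, with identical values because they share their reads, and Rn7sk, the RNA that holds the elongation factor P-TEFb inactive, was at 57194 ± 976 TPM. These 3 genes made up 37.8% ± 0.467 of TPM and 5.68% ± 0.196 of the expected counts on genes. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 followed at 38946 ± 307 and 28926 ± 891 TPM. Nuclear protein-coding genes held 41.6% ± 0.60 of TPM and 79.3% ± 0.144 of counts, and mitochondrial genes held 7.74% ± 0.00591 of counts. That mitochondrial share leaves out counts given to near-identical nuclear copies. In replicate 1, Gm28661 had 90369 counts beside 2048 on mt-Co2, Gm10925 75043 beside 34732 on mt-Atp6 and Gm28437 65385 beside 24144 on mt-Co3. Whether those reads came from mitochondrial transcripts was not tested. The short RNAs were near 0 in the second quantification, where nuclear protein-coding genes held 74.3% ± 0.0815 of TPM, so a TPM of the gene quantification is lowered by the short RNAs it is divided with.

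Markers of granule cells and of CA1 and CA3 pyramidal cells were detected in full, and those of CA2 and mossy cells in part. The glutamatergic list, led by Camk2a, Chn1 at 725 ± 16.5 TPM and the postsynaptic calmodulin-binding protein Nrgn at 638 ± 31.6 TPM, had a median of 165 TPM with 12 of 12 members detected, and of 166 TPM in replicate 1 and 163 TPM in replicate 2. Dentate granule cell genes had a median of 34.6 TPM with 12 of 12 detected, among them Prox1, a transcription factor of granule cells, at 40.5 ± 1.56 TPM, with C1ql3 at 73.4 ± 4.21 TPM and Calb1 at 70.4 ± 5.71 TPM. CA1 genes had a median of 26.1 TPM with 10 of 10 detected, led by Mpped1 at 68.9 ± 2.98 TPM and Wfs1 at 58.2 ± 6.00 TPM. CA3 genes had a median of 33.2 TPM with 10 of 10 detected, led by Nnat at 223 ± 5.08 TPM and Dkk3 at 109 ± 1.22 TPM. Dcn of the CA1 list is also on the meninges list, and Nnat of the CA3 list on the imprinted list. Detection therefore does not by itself mark a cell type. The CA2 list had a median of 7.75 TPM with 8 of 10 detected, the mossy cell list 3.0 TPM with 6 of 8, and the subiculum list 15.4 TPM with 8 of 8.

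Interneuron and glial markers were present throughout. The GABAergic list had a median of 20.5 TPM with 20 of 20 detected, led by Sst, which encodes somatostatin, at 164 ± 4.87 TPM and Gad1, which makes GABA from glutamate, at 143 ± 4.97 TPM. Astrocyte genes had a median of 82.4 TPM with 14 of 14 detected, with glutamine synthetase, Glul, at 749 ± 8.57 TPM and the glutamate transporter Slc1a2 at 690 ± 39.1 TPM. Oligodendrocyte and myelin genes had a median of 43.7 TPM with 15 of 15 detected, led by Mbp, which encodes myelin basic protein, at 433 ± 33.0 TPM. Precursors of these cells had a median of 7.11 TPM with 13 of 13 detected. Microglial genes had a median of 12.8 TPM with 15 of 15 detected. The endothelial list had a median of 8.87 TPM with 13 of 13, and the pericyte and smooth muscle list 3.18 TPM with 9 of 11.

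**Figure D1:**
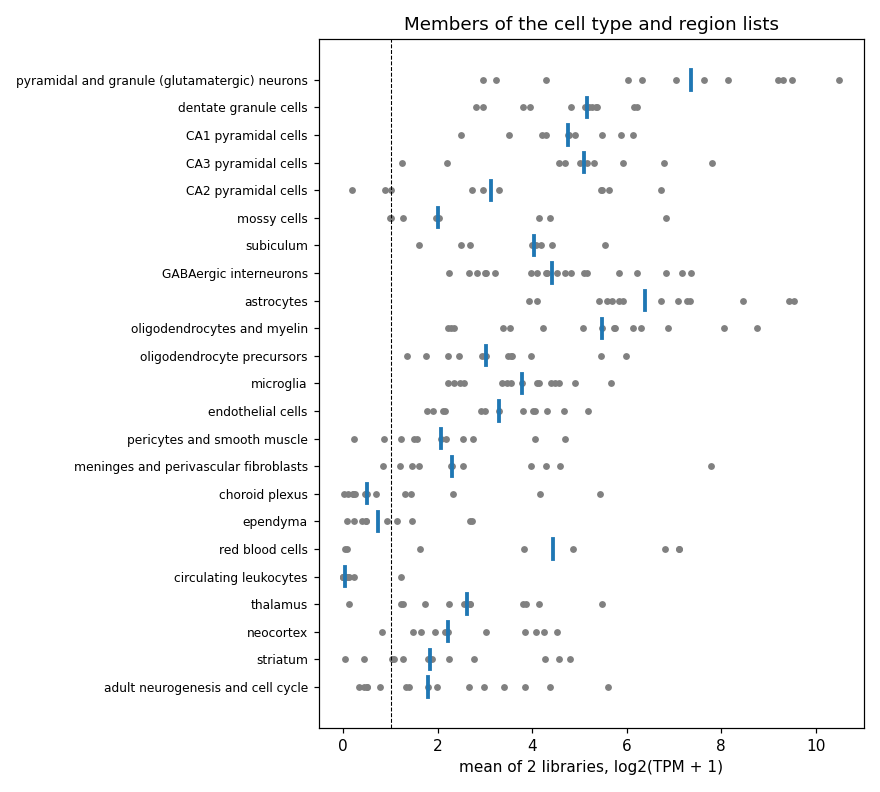
Levels of the members of 23 cell type and region lists. Each point is 1 gene at the mean of 2 libraries on the log2(TPM + 1) scale, blue bars are list medians and the dashed line marks 1 TPM. The glutamatergic list has the highest median at 165 TPM, and the leukocyte list the lowest at 0.0300 TPM.

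Lists of tissue next to the hippocampus had medians of 0.407 to 5.13 TPM, a range that also held the mossy cell list at 3.0 TPM. Most members of the meninges, thalamus, neocortex and striatum lists were detected. Red blood cell genes stood higher. Some members are shared with lists of hippocampal cells, such as Calb2 with mossy cells and Lamp5 with interneurons, so detection does not by itself mark such tissue. The choroid plexus list had a median of 0.407 TPM with 5 of 14 detected, the ependyma list 0.652 TPM with 3 of 10, and the meninges and fibroblast list 3.94 TPM with 10 of 11. Ptgds, which meningeal cells and oligodendrocytes express, was at 220 ± 0.410 TPM. The red blood cell list had a median of 20.7 TPM with 6 of 8 detected, with Hbb-bs at 136 ± 6.83 TPM, while circulating leukocytes had a median of 0.0300 TPM with 1 of 10 detected. The thalamus list had a median of 5.13 TPM with 11 of 12, the neocortex list 3.62 TPM with 10 of 11 and the striatum list 2.58 TPM with 8 of 12. The list of other organs, a background, had a median of 0.108 TPM with 3 of 12 detected. Genes of adult neurogenesis and the cell cycle had a median of 2.48 TPM with 10 of 15 detected.

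Synaptic genes stood high among detected genes. Presynaptic release genes had a median of 220 TPM with 17 of 17 detected, led by Snap25 at 902 ± 31.3 TPM, and postsynaptic density genes had a median of 97.7 TPM with 18 of 18 detected, with Dlg4 at 358 ± 5.94 TPM. Both medians lay at percentile 100 of the random lists. In the other lists of this kind the percentile was 99.1 for AMPA, NMDA and kainate receptors, 99.6 for GABA-A receptors, 91.3 for metabotropic glutamate receptors, 99.97 for sodium and potassium channels and 4.05 for neuropeptides. Percentile 100 was not particular to synaptic genes. The glutamatergic, astrocyte, ribosomal protein and nuclear respiratory chain lists, among others, reached it too. AMPA, NMDA and kainate receptor subunits had a median of 31.9 TPM with 15 of 16 detected, led by Gria1 at 295 ± 14.9 TPM and Gria2 at 276 ± 18.9 TPM. GABA-A receptor subunits had a median of 38.2 TPM with 12 of 15, metabotropic glutamate receptors 27.3 TPM with 7 of 8, and sodium and potassium channels 44.3 TPM with 18 of 18. Neuropeptide genes had a median of 6.26 TPM with 16 of 18, with Cck at 283 ± 16.8 TPM.

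Of the lists of cell state, heat shock genes had a median of 52.2 TPM with 12 of 12 detected, immediate early genes 8.94 TPM with 19 of 20, clock genes 18.9 TPM with 17 of 18, glucocorticoid responsive genes 20.3 TPM with 14 of 14 and interferon responsive genes 0.810 TPM with 6 of 14. The MHC class I list had a median of 7.29 TPM with 6 of 7. Alzheimer and Parkinson disease genes had a median of 66.6 TPM with 16 of 16, led by Apoe at 947 ± 48.0 TPM and App at 498 ± 2.54 TPM. Imprinted genes had a median of 22.9 TPM with 28 of 33, and long noncoding RNAs 48.8 TPM with 17 of 17, led by Malat1 at 4800 ± 856 TPM. Small noncoding RNA genes had a median of 79.3 TPM with 11 of 13. Mitochondrially encoded protein genes had a median of 1796 TPM with 13 of 13, nuclear respiratory chain genes 138 TPM with 20 of 20 and cytosolic ribosomal protein genes 181 TPM with 25 of 25.

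The sex-linked genes were those of male tissue, as labelled. Of 7 Y-linked genes, 4 were detected, with a list median of 7.63 TPM. Eif2s3y was at 27.6 ± 0.672 TPM, Ddx3y at 18.7 ± 0.403 TPM, Uty at 9.41 ± 0.0424 TPM and Kdm5d at 7.63 ± 0.820 TPM. Sry and Zfy1 had 0 counts in both libraries, which allows up to 0.123 TPM for Sry and 0.0490 TPM for Zfy1 in replicate 1. Usp9y had a TPM of 0.0400 in replicate 1 and 0 in replicate 2. Xist, the RNA that coats the inactive X chromosome, was at 0.0400 TPM in replicate 1 and 0.0100 TPM in replicate 2, and the X inactivation list had a median of 0.0900 TPM with 0 of 2 detected. Genes that escape X inactivation had a median of 30.5 TPM with 4 of 4 detected.

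The 2 libraries agreed closely but differed by more than sampling noise. Across 15554 genes, Pearson's r was 0.985 and Spearman's rho 0.988. The chi-square statistic over genes was 4.09 per degree of freedom with 20087 degrees of freedom, and over spike-ins it was 3.11 with 46, so the added synthetic RNAs also differed by more than sampling noise. The common biological coefficient of variation was 4.24% for genes, estimated with edgeR, and 2.91% for spike-ins. Among 13916 genes with at least 50 counts in both, the SD of the log2 ratio was 0.20. Spike-ins took 0.491% of counts in replicate 1 and 0.511% in replicate 2, and 41 of 96 ERCC entries reached 1 TPM in both. Their levels correlated between the libraries at r = 0.999 across 97 spike-in entries, and ERCC-00002 and ERCC-00130 had the highest means.

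**Figure D2:**
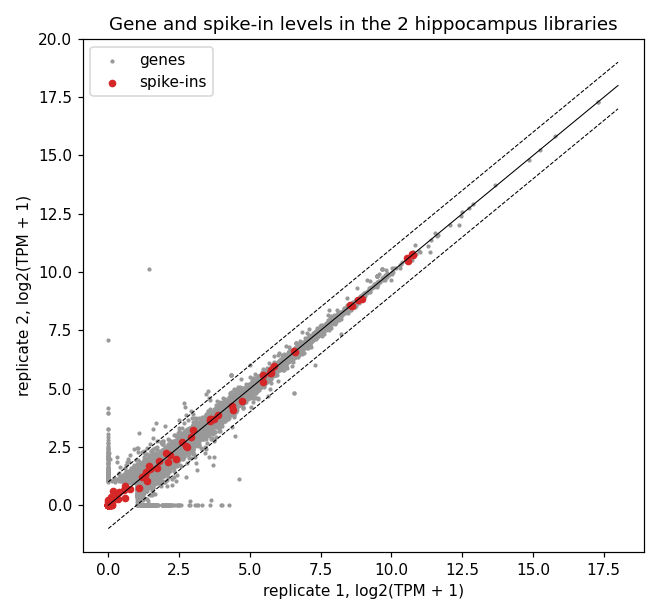
Level of each gene (grey) and spike-in (red) in replicate 1 against replicate 2, both on the log2(TPM + 1) scale. The solid line marks equal levels and the dashed lines a 2-fold difference on that scale, and across genes Pearson's r was 0.985.

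Few genes were 2-fold apart. Of the 13916 genes, 17 were at least 2-fold higher and 21 at least 2-fold lower in replicate 2, against 10 and 6 in TMM-scaled counts and 26 and 22 in the second quantification, with 1 library on each side and so no replicate check. Ttr, the thyroxine carrier made by the choroid plexus, which lies on chromosome 18 from 20665280 to 20674321, was at 10.6 TPM in replicate 1 and 23.1 TPM in replicate 2, a log2 ratio of 1.12. The clustered protocadherin genes Pcdhb2 and Pcdhb3, cell adhesion genes on chromosome 18, had log2 ratios of 1.54 and 1.14. Gm49388 had the highest ratio at 2.19, and Gm5641 the lowest at -2.37. Nid2, Sgms2, Myl12b (ENSMUSG00000117098.1, 1 of 2 genes with that symbol), Ttn, Gm11847, Rpl15-ps3 and Fbxl12os were the other genes of the 10 highest ratios, and Gm10240, Gm13370, Wdfy4, Gm28635, Gm45140, Spink10, Plk4, mt-Co2 and Igsf9 the other genes of the 10 lowest. Gm10240 and Gm13370 had identical counts, and share their reads. Of the 38 genes, 15 were also 2-fold apart in TMM-scaled counts, and 4 of these, Pcdhb2, Pcdhb3, Ttr and Gm49388, also in the second quantification. The ependymal gene Dnah11 had a log2 ratio of -1.21 at 68 and 52 counts, but of -0.38 in TMM-scaled counts and -0.49 in the second quantification. The mitochondrial gene mt-Co2 had 2048 and 862 counts, and shared 99.5% of its 31-base words with the nuclear copy Gm28661.

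Of 45 lists with a member at 50 counts, 11 had a median ratio outside 95% of the matched random lists. A share of 5% of 45 lists is 2.25, while 4 of 50 simulated lists with no shift were outside, and members of a real list may vary together, which was not tested. Immediate early genes, which neurons switch on within minutes of activity, were higher in replicate 2 with a median log2 ratio of 0.22 and 14 of 19 members above 0. Npas4 had a log2 ratio of 0.57, Nr4a1 0.48, Fos 0.42 and Arc 0.37, while Dusp5 had -0.39. Red blood cell genes had a median of 0.14 with 5 of 6 members above 0. Long noncoding RNAs were lower, with a median of -0.21 and 16 of 17 members below 0, among them Malat1 at -0.37 and Meg3 at -0.30. Glucocorticoid responsive genes had a median of -0.19 with 9 of 14 below 0, led by Hif3a at -0.67 and Zbtb16 at -0.39. Heat shock genes had a median of -0.11 with 11 of 12 below 0. These 5 lists stayed outside the range in TMM-scaled counts, at a count minimum of 10 and in the second quantification.

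The other 6 lists lost that place in at least 1 of those settings. Oligodendrocyte and myelin genes had a median of -0.15 with 11 of 15 members below 0, and their precursors -0.16 with 10 of 12 below 0, and in the second quantification they lay at percentiles 12.1 and 19.1. MHC class I genes had a median of 0.16 and lay at percentile 91.2 in the second quantification and 92.1 in TMM-scaled counts. Microglial genes had a median of 0.07 and cytosolic ribosomal protein genes 0.03, at percentiles 96.7 and 96.8 in the second quantification. Mitochondrially encoded protein genes had a median of -0.09 with 13 of 13 below 0, and lay at percentile 3.92 in the second quantification. In TMM-scaled counts their median was -0.04 at percentile 0, with mt-Co1 at 0.008 and mt-Nd6 at 0.03 and the other members below 0. There mt-Atp6 had -0.48 alone and -0.02 when summed with its nuclear copy Gm10925. With random lists matched on length as well, ribosomal protein genes lay at percentile 74.1, and with GC content the precursors lay at percentile 2.60. Over the 13916 genes the median log2 ratio was -0.04.

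The medians of the other 34 lists lay within the random range, and the ratios given here are median log2 ratios. Among neurons, the median was 0.02 for glutamatergic genes, 0.03 for dentate granule cells, -0.03 for CA1, -0.13 for CA3, 0.02 for CA2, -0.03 for mossy cells, 0.04 for the subiculum and -0.04 for GABAergic genes. CA3 genes, with 9 of 10 members below 0, lay at percentile 3.30, and at percentile 2.23 in TMM-scaled counts, where dentate granule cell genes lay at percentile 99.96 with a median of 0.11, glutamatergic genes at percentile 98.8 and sodium and potassium channels at percentile 0.880. In the second quantification the dentate list turned to -0.02 at percentile 55.6, CA3 genes lay at percentile 6.25, and choroid plexus genes were outside the range at percentile 99.4 with a median of 0.27, as were striatum genes at percentile 98.2 and endothelial genes at percentile 97.7. At a count minimum of 10, CA3 genes lay at percentile 2.48, striatum genes at percentile 99.7 and small noncoding RNA genes at percentile 99.99. With GC content matched, CA3, presynaptic and postsynaptic genes lay at percentiles 2.31, 2.33 and 1.71 and nuclear respiratory chain genes at percentile 98.5, and with length matched, dentate genes lay at percentile 99.1. The median was -0.02 for astrocytes, 0.01 for endothelial cells, 0.04 for pericytes and smooth muscle, 0.00 for meninges and fibroblasts, 0.08 for the choroid plexus and 0.08 for ependyma. It was -0.03 for the thalamus, -0.02 for the neocortex, 0.03 for the striatum and 0.00 for adult neurogenesis and the cell cycle. Synaptic lists had medians of -0.05 for AMPA, NMDA and kainate receptors, -0.12 for metabotropic glutamate receptors, -0.01 for GABA-A receptors, -0.05 for presynaptic release genes, -0.07 for the postsynaptic density and -0.09 for sodium and potassium channels. Neuropeptide genes had -0.01, Alzheimer and Parkinson disease genes -0.05, imprinted genes -0.03, clock genes -0.07, interferon responsive genes -0.09, small noncoding RNA genes 0.04 and nuclear respiratory chain genes 0.03. Y-linked genes had 0.02, genes that escape X inactivation -0.01, and the list of other organs, with 1 member, -0.01. Leukocyte and X inactivation genes had no member with enough counts. Small medians carry no firm direction. In TMM-scaled counts the sign turned for 13 of these lists, among them metabotropic glutamate receptors at 0.02, interferon responsive genes at 0.03, CA1 genes at 0.05 and neuropeptides at 0.07, and the others were astrocytes, mossy cells, meninges, thalamus, neocortex, neurogenesis, imprinted genes, genes that escape X inactivation and other organs. In the second quantification it turned for 12, which were CA1 genes at 0.06, GABA-A receptors at 0.07, interferon responsive genes at 0.05, the subiculum at -0.03, dentate granule cells, astrocytes, mossy cells, meninges, neuropeptides, imprinted genes, genes that escape X inactivation and other organs.

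**Figure D3:**
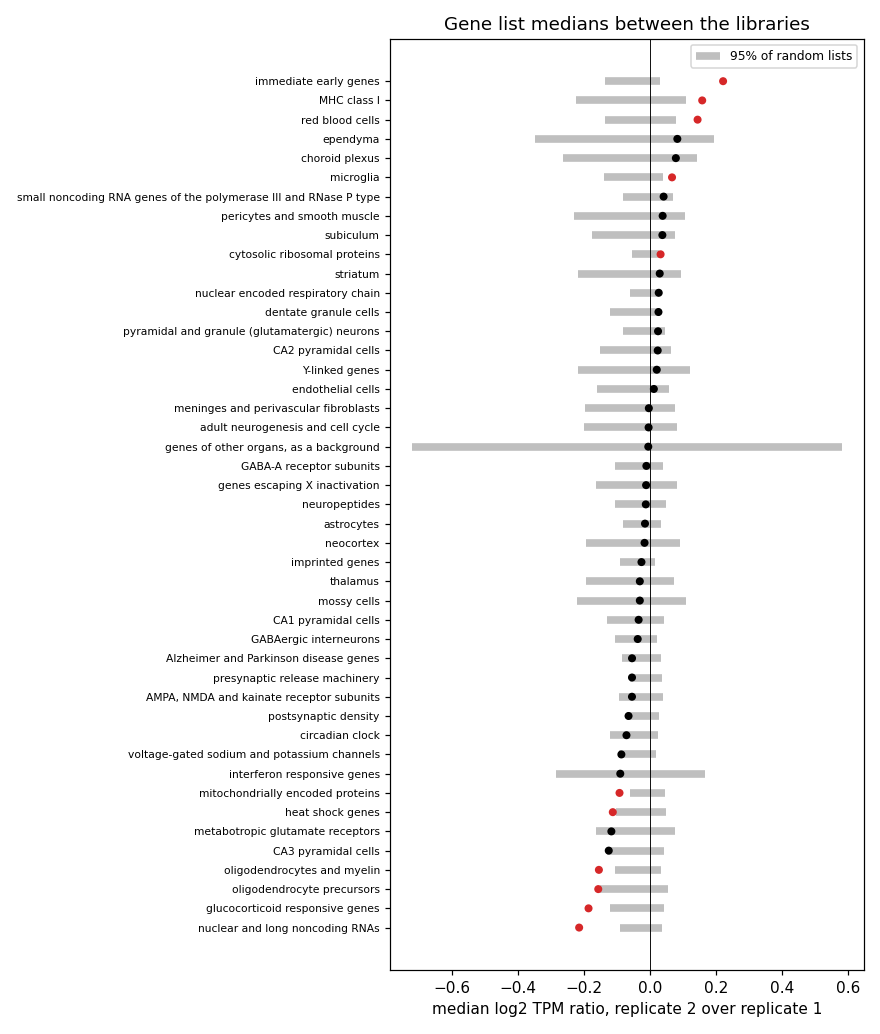
Median log2 TPM ratio of replicate 2 over replicate 1 for 45 lists, with points in red where the median lies outside 95% of 10000 matched random lists (grey bars). Immediate early genes lie highest at 0.22, and long noncoding RNAs lowest at -0.21.

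Transcript levels depended more on the quantification than on the library. Between the first and second quantification, Pearson's r across transcripts was 0.727 in replicate 1 and 0.730 in replicate 2. Between the libraries it was 0.954 in the first and 0.930 in the second quantification. Over 11997 detected genes with several transcripts, the most abundant transcript was the same in both quantifications for 8938 genes in replicate 1 and 8911 in replicate 2, and in both libraries for 10630 genes in the first quantification. The count of single-transcript genes in the second quantification fell with transcript length, from a median of 0.976 of the first at 1001 to 2000 nucleotides to 0.249 at 401 to 500 nucleotides.

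**Figure D4:**
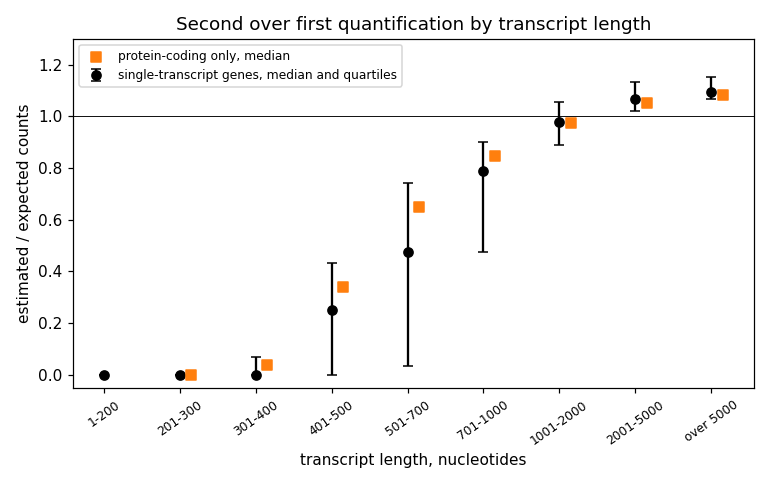
Ratio of estimated counts in the second quantification to expected counts in the first, by transcript length, for genes with 1 transcript and at least 50 counts. Black points are medians with quartiles and orange squares medians of protein-coding genes, and the median is 0 up to 400 nucleotides and 1.07 at 2001 to 5000 nucleotides.

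Of 39 isoform genes, 34 had the same most abundant transcript in both quantifications. App-201 held 91.6% ± 0.169 of the App transcripts, Snap25-201 held 88.0% ± 0.158 of Snap25 and Camk2b-209 held 85.8% ± 0.419 of Camk2b. In 20 genes the leading transcript held under 50%. The leading transcript of Mbp, Mbp-211, held 70.2% ± 0.537 in the first and 37.9% ± 0.509 in the second quantification. Grin1, Dlg4, Pkm, Syn2 and Meg3 had different leading transcripts. The median SD of a share between the libraries was 1.03 percentage points, and the median difference between the quantifications was 5.99 percentage points.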

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

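Entries known by number only, about which the sources used here say nothing more, are outside the gene results. Summed over all 26248 entries, they took 4.91 expected counts in replicate 1 and 2.00 in replicate 2. The limit of 3 counts holds for a single entry with a count of 0 and does not bound this sum. What these entries are was not tested.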

How the results depend on the processing

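The alternatives that match lists on length or GC content, and those for the share of protein-coding genes, were added after the data were seen. The number of detected genes stayed within 1.5 times across thresholds and quantifications, and was 14965 to 15149 with 1 library left out. The protein-coding share of TPM was 79.3% in expected counts and 74.3% in the second quantification, against 41.6%, since both give short RNAs less weight. The spike-in share was 0.880% in TPM. The Pearson correlation between the libraries was 0.957 with a pseudocount of 0.1, 0.995 with no filter and 0.995 for nuclear protein-coding genes. The coefficient of variation was 4.96% with no filter. Genes 2-fold apart numbered 265 at a count minimum of 10, with 113 higher and 152 lower in replicate 2, 6 at a minimum of 200 and 16 in TMM-scaled counts, against 38. The Pearson correlation of transcripts between the quantifications was 0.618 with a pseudocount of 0.1 and 0.597 for transcripts of at least 1 TPM. Among the genes named by the rule, the sign turned in TMM-scaled counts for the log2 ratio of Wdfy4 at 0.21. It turned in the second quantification for the log2 ratio of mt-Co2 at 0.0120 and the log2 ratio of Gm11847 at -0.94, the latter from 20.3 and 10.8 counts. Ratios of the named genes in the second quantification needed 10 counts in both libraries. That left out genes such as Gm5641, at 0 counts there in both libraries, and Myl12b (ENSMUSG00000117098.1). This Myl12b gene was at 7.78 TPM in replicate 1 and 0.696 TPM in replicate 2 in that quantification. That is the opposite direction to the gene quantification, where it was higher in replicate 2. Apart from the causes named here, the cause was not tested. The leading isoform share moved by over 1 SD in 37 of 39 genes. Leaving out replicate 1 moved the median TPM of 5 of 47 lists by more than its spread, and leaving out replicate 2 that of 5. Lists outside the random range numbered 14 in TMM-scaled counts, 13 at a count minimum of 10 and 8 in the second quantification, of which 10, 10 and 5 were among the 11. Random lists drawn in 5 repeats put 11 lists outside the range each time, while with matching on expression and GC content the number was 13 to 15, so calls near the percentiles depend on the draw. Results that compare the libraries cannot leave 1 out. Low counts limit the ratios.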

Other observations

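Clustered protocadherins of the alpha family, neuronal adhesion genes read from alternative promoters on chromosome 18, were lower in replicate 2. This family was chosen after its values were seen, as 1 of 11 families. All 14 alpha gene identifiers, 2 of them with the symbol Pcdha11, were detected, 13 of 14 had a negative ratio, and the median log2 ratio was -0.48, at percentile 0 of matched random lists, with -0.47 in TMM-scaled counts and -0.47 in the second quantification. The most abundant member, Pcdhac2, had a log2 ratio of 0.03, and the family's share of counts went from 0.0194% to 0.0164%. Since the family was picked for its values, the percentile describes it and is no test. The beta family had a median of -0.09 at percentile 37.1 and the gamma family -0.06 at percentile 42.2. The beta median hides a split. The neighbouring genes Pcdhb2 to Pcdhb7 had log2 ratios of 0.16 to 1.54, while 13 of 21 beta members were below 0. That run of genes was picked after its values were seen. The alpha genes share their constant exons, so reads can move among them. Replication-dependent histone genes had a median of 0.02 at percentile 99.7 over 45 members, and in the second quantification of 0.11 at percentile 100. For families the random lists were matched on expression and not on length. Several short histone genes, such as Hist1h4k, had no ratio in the second quantification, so that median covers a different set of members. Of the other families, muscarinic receptors were led by Chrm1 at 76.0 ± 1.93 TPM, adrenergic receptors by Adra1d at 39.9 ± 0.368 TPM and serotonin receptors by Htr1a at 15.9 ± 0.403 TPM. Of 1135 olfactory receptor genes 1 was detected, and of 39 Hox genes 0.

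The tests on short RNAs, on mt-Co2 and on transcript length in the 2-fold genes were chosen after the results were seen, while the test of counting noise was chosen before. The tests of length and GC content in the lists were added after the data were seen, with their outcomes stated before they were run with 10 expression bins, and were repeated with 20 bins after that. No biological explanation was tested, since the design has 1 group.

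Short noncoding RNAs were near 0 in the second quantification. For Rn7s1, Rn7s2 and Rn7sk, the 41 other genes that share a 31-base word with them gained -0.0141% of the lost counts. Those 41 genes themselves fell from 519 to 18.3 counts. Since they lost counts too, this test cannot decide whether reads were shared between copies. Sharing is argued against for 8 of 104 short noncoding genes, which share no word with another gene and had a median ratio of 0. The others stay open. A loss of reads on transcripts shorter than the fragments may account for it, since protein-coding genes of at most 400 nucleotides had a median ratio of 0.0140 over 13 genes, and spike-ins under 300 nucleotides had 0 of their 50 expected counts.

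Of the 38 genes at least 2-fold apart, 23 were under 2-fold in TMM-scaled counts, and assignment of reads to transcripts of different length may account for these. The other 15 stay open. Of these 15, 10 are pseudogenes or carry a Gm name, and 4 were also 2-fold apart in the second quantification. Poisson draws gave a mean of 0.160 genes at least 2-fold apart, but the draws cover counting error only. The spread between single samples holds more than that, so the draws decide nothing here. For mt-Co2, less transcript and reads shared with the nuclear copy Gm28661 cannot be told apart, since the genes share 99.5% of their 31-base words. The log2 ratio was 0.0120 in the second quantification and 0.00751 for the summed count, of which mt-Co2 held 2.22%, too little to move the sum.

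Of the 11 shifted lists, 10 stayed outside the range against random lists matched on expression and length, and 10 against lists matched on expression and GC content, which argues against either trend as the whole cause. Over 5 repeated draws the numbers were 9 to 10 and 10 to 11. A first version of the matching, with 10 expression bins and at least 3 members per list, kept fewer of them for GC content, and 10 bins without that minimum kept 9 to 10 in repeated draws, and heat shock genes then lay at percentile 2.67. Ribosomal protein genes moved to percentile 74.1 with length. Dissection, time of day and activity of the animals were not tested and may differ between the libraries.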
